A study of Mus musculus with 4 samples.

How the data were processed

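Gene expression was measured in mouse intestinal organoids, 3-dimensional cultures of intestinal epithelium grown in Matrigel, on 4 Affymetrix arrays, 1 for each combination of Tacc3 genotype (wt/wt or fl/fl) and day (4 or 6). Per the labels' protocols, the cultures received 4OHT (4-hydroxytamoxifen) for 24 hours, total RNA was isolated with a column kit, and biotinylated cRNA was made from 100 ng of it with a 3' in vitro transcription kit. The group of each array was taken from its title. The sample descriptions call the day 4 cultures normal and the day 6 cultures Apc-deficient, whereas the series design text says that 4OHT was used to recombine both genes before collection at either day. The Apc state of each array is therefore not settled by the labels and was not used to form groups.

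The deposited values are 1 linear intensity for each of 45101 probe sets per array, as the values themselves show. The software that summarised the probes, the background correction and the normalization are not given in the sources used here. Array medians between 15.4 and 17.7 and 95th percentiles between 303.0 and 439.0 show that the 4 arrays do not share 1 intensity distribution. The number of arrays limits the precision: with 1 array per group, no difference has a replicate check.

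The deposited intensities were analysed as log2(intensity + 16), so that all differences are on that scale, which understates the differences of dim genes. No further normalization was applied. The platform's gene table gives 1 gene symbol for 34958 probe sets and several for 932, and does not list 9211, of which 9160 are not Affymetrix control probe sets. Symbols were updated through the Entrez ID with a RefSeq table of the GRCm38.p6 assembly, which matched 34754 of the probe sets with 1 symbol; that table was used only for names and for which genes are neighbours. Each gene was represented by its probe set with the highest mean over the 4 arrays, without control probe sets and probe sets of several genes, which gave 18193 genes. Counts and named genes use the 11392 genes whose mean reached the median of all probe sets (log2 5.04, an intensity of 16.9). Among 4816 genes with several probe sets above that level, 64 had probe sets that differed 2-fold between the days in opposite directions.

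Differences were taken between genotypes within each day (fl/fl minus wt/wt), between days within each genotype (day 6 minus day 4), and between the genotype differences of the days. The pair of genotype differences shares no array, and neither does the pair of day differences. A gene was counted where its difference was at least 2-fold (1 on the log2 scale). Such counts describe size only, and no p-value was computed for them. Overlaps of counts in the same direction are given beside the number expected from independent lists, the product of the 2 counts divided by the number of genes.

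In all, 26 gene lists were fixed before the data were examined: the recombined genes, p53 targets, senescence and secretory phenotype, mitosis and G2/M, S phase and DNA replication, TACC3 spindle partners, Wnt/beta-catenin targets, intestinal stem cell, Paneth cell, goblet cell, enteroendocrine cell, tuft cell, enterocyte, fetal and regenerative epithelium, interferon response, apoptosis regulators, unfolded protein and integrated stress response, heat shock and immediate early, cholesterol synthesis, hypoxia and glycolysis, Notch pathway and secretory fate, mesenchymal cell, immune cell, endothelial cell, sex chromosome transcripts and housekeeping. For every list, the median difference of its measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 10 bins. A list was said to stand apart where it lay below the 2.5th or above the 97.5th percentile in both arrays' comparisons of a pair. The percentile describes these arrays, and the random lists treat genes as independent, which members of a pathway are not. About 5% of lists would lie outside in a single comparison by chance if members were independent. The share can be larger where members vary together. More lists than 5% lay outside between genotypes at day 4 and at day 6. At day 4 these were the recombined, Paneth, goblet, unfolded protein, hypoxia and mesenchymal lists. At day 6 they were the recombined, p53, mitosis, spindle partner, stem cell, enteroendocrine, tuft, enterocyte, heat shock, cholesterol, hypoxia and sex chromosome lists. A percentile outside the range at a single day thus does not mark a list as unusual among the lists.

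The genes named were set by a rule fixed at the same time: Tacc3 and Apc; up to 12 genes in each direction with the largest mean genotype difference among those 2-fold in the same direction at both days; 10 genes in each direction by mean day difference among those 2-fold in both genotypes; the 5 highest and 5 lowest differences of the genotype differences; in each list, up to 4 members with the largest mean genotype difference and 4 with the largest mean day difference in either direction; and all members of the recombined, sex chromosome and housekeeping lists. Genes named outside this rule are said to be so.

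Alternatives planned at that stage were quantile normalization and centring of each array on the median of its genes above the filter. Others were no low-value filter or one at the 70th percentile, the mean of a gene's probe sets, and leaving out probe sets whose suffix marks possible cross-hybridization (x_at and s_at). The rest were pseudocounts of 1 and 64, raising values to the 20th percentile, thresholds of 1.5-fold and 3-fold, pairing the genotypes across days, and an additive limma fit of genotype and day, which has 1 residual degree of freedom. The restriction of lists to members above the filter was added after the data had been seen.

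The counting and list steps were tested on simulated data for the comparison of genotypes at both days, with 18193 genes in each of 20 simulations. The 2-fold rule was applied to the 11392 genes above the filter, from which the changed genes were drawn. It kept 0.9% of genes changed 1.5-fold, 26.0% of genes changed 2-fold, 93.8% of genes changed 3-fold and 100.0% of genes changed 4-fold, and a mean of 0.05 of 11192 unchanged genes per simulation. The lists were tested on the mean genotype difference of both days. Of 20 unchanged lists of 34 genes, 2 lay outside the 2.5th to 97.5th percentile, and 20 of 20 lists raised by 0.2 on the log2 scale lay above it. The simulated noise was normal and independent between genes, with no shift between arrays. The rates hold only for such data, not for genes that vary together. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.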

Results

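Expression was profiled in mouse intestinal organoids that were wt/wt or fl/fl at Tacc3, at day 4 or day 6. The cultures received 4-hydroxytamoxifen, the drug used here to induce recombination of Apc and Tacc3. The titles do not say from which event the days were counted. Tacc3 encodes a spindle protein that stabilises microtubules in mitosis, and Apc encodes the tumour suppressor that limits beta-catenin in the Wnt pathway. There were 4 groups with 1 array each, so no value below has a replicate error, and differences were called by their size, without a p-value. Median intensities were 17.7 in wt/wt and 16.5 in fl/fl organoids at day 4, and 15.8 and 15.4 at day 6; the 95th percentiles were 303.0, 361, 424 and 439.0. On the log2 scale, the 2 genotypes correlated across all probe sets at r = 0.980 at day 4 and 0.985 at day 6, and arrays of different days at 0.918 to 0.945; probe sets are not independent replicates.

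The control probe sets differed between the days. The 5' to 3' intensity ratio of Actb was 0.0610 in wt/wt and 0.0627 in fl/fl organoids at day 4, against 0.180 and 0.261 at day 6. The ratio of Gapdh was 0.208 and 0.142 at day 4, against 0.411 and 0.524 at day 6. A low ratio is a usual sign of degraded RNA or of short labelled cRNA. The bacterial hybridization controls were a median 2.55-fold brighter at day 4 than at day 6 in wt/wt and 2.44-fold in fl/fl organoids, the poly-A spike-ins 2.19-fold and 2.21-fold, and 18S ribosomal RNA 3.71-fold and 2.58-fold. Within a day, the hybridization controls were 1.42-fold (day 4) and 1.41-fold (day 6) brighter in wt/wt than in fl/fl organoids, and the poly-A spike-ins 1.66-fold and 1.69-fold. The same ratio for 18S ribosomal RNA was 0.986 at day 4 and 0.686 at day 6, lower in wt/wt than in fl/fl organoids. None of the alternative scalings used these controls, so the directions of genes and lists relative to them were not examined.

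Tacc3 was lower in fl/fl organoids on both days. Its brightest probe set, 1417450_a_at, had an intensity of 184 in wt/wt and 59.8 in fl/fl organoids at day 4, and of 167 and 49.7 at day 6, so that fl/fl organoids held 32.5% and 29.8% of the wt/wt level (log2 differences of -1.40 and -1.47). Probe set 1455834_x_at held 48.9% and 50.7% of the wt/wt level, from 32.1 and 45.5 in wt/wt organoids. Probe set 1436872_at, close to the background with 15.7 and 22.6 in wt/wt organoids, held 80.4% and 87.2%. With the mean of the probe sets in place of the brightest, the differences of -0.72 and -0.75 no longer reached 2-fold. The labels do not say which exons of Tacc3 are floxed, so it is not known whether these 3' probe sets lie in the deleted part.

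Apc showed no common direction. Probe set 1420956_at read 27.9 in wt/wt and 53.5 in fl/fl organoids at day 4 and 122 and 150 at day 6, and 1435543_at went the same way, from 28.5 and 45.1 to 94.7 and 97.1. Probe set 1420957_at went the other way, from 81.9 and 75.0 at day 4 to 20.8 and 26.4 at day 6, and 1450056_at stayed below the filter on average, between 10.1 and 17.3. Between genotypes, the brightest Apc probe set differed by 0.66 at day 4 and 0.27 at day 6 on the log2 scale, short of 2-fold. As with Tacc3, the position of these probe sets relative to the floxed exons is not known, and the mean of the Apc probe sets differed by only 0.43 and 0.35 between the days.

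**Figure D1:**
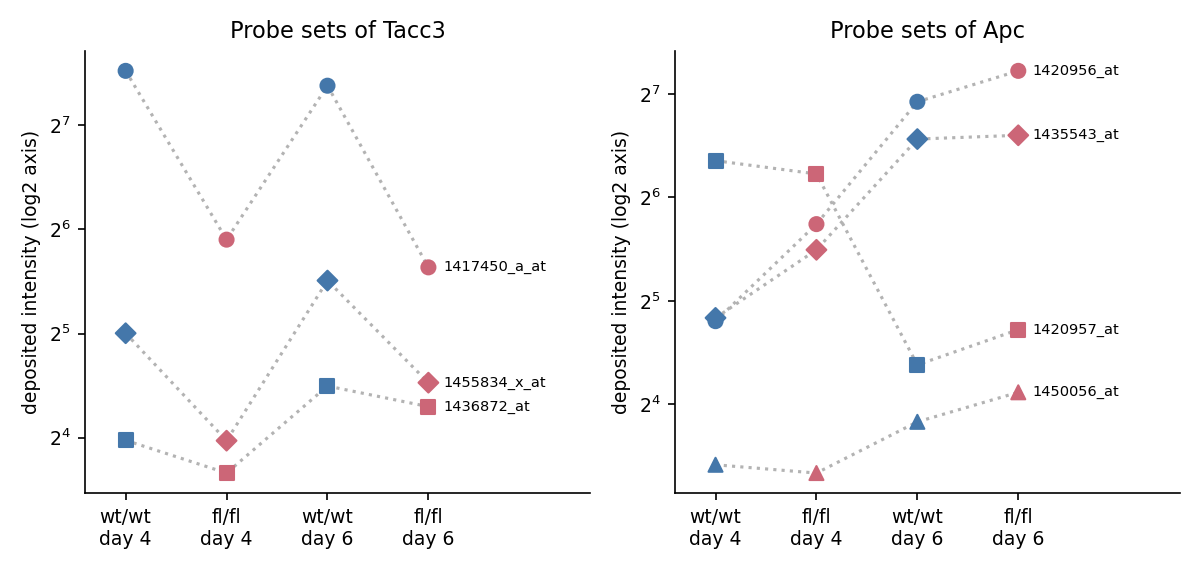
Deposited intensity (log2 axis) of each probe set of Tacc3 (left) and Apc (right) on the 4 arrays, wt/wt in blue and fl/fl in red; each point is 1 array, a marker shape stands for a probe set, and dotted lines join points of 1 probe set. The brightest Tacc3 probe set reads 184 and 167 in wt/wt against 59.8 and 49.7 in fl/fl organoids, while Apc probe sets move in opposite directions between the days.

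The comparison of fl/fl with wt/wt organoids at each day addresses what else differed where Tacc3 was floxed. Besides Tacc3, 2 genes differed 2-fold in the same direction on both days. Slc15a2, which encodes a proton-coupled peptide transporter, was higher in fl/fl organoids by 1.28 at day 4 and 2.46 at day 6 on the log2 scale, with intensities of 63.1 against 176 and of 32.9 against 253. Erdr1 was lower, with differences of -2.12 and -2.80 and intensities of 4377 against 994 and of 2210 against 303. The other Erdr1 probe set above the filter differed by -1.35 and -0.29, and the other 2 probe sets of Slc15a2 lay below the filter with differences of -0.08 and -0.02 and of -0.06 and -0.17. The Erdr1 value is uncertain, because its brightest probe set is of the x_at kind that can bind several transcripts. Without x_at and s_at probe sets Erdr1 was no longer 2-fold at day 6 (-0.29). The probe set then used read 20.2 in wt/wt and 13.5 in fl/fl organoids at day 6, close to the filter's 16.9. At such intensities the log2(intensity + 16) scale leaves little room for a 2-fold fall, so this value neither bears out nor contradicts the brighter probe set. Slc15a2 was no longer 2-fold at day 4 with pseudocount 64 (0.92), nor on either day with the mean of its probe sets (0.38 and 0.76).

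Targets of p53 were higher in fl/fl organoids by a small amount at day 6 and in the mean of both days, but not apart from random lists at day 4. The median of 34 measured members was 0.22 higher at day 4 (percentile 78.45 of random lists), 0.21 higher at day 6 (percentile 99.8) and 0.22 higher in the mean of both days (percentile 99.4). Random lists had a median of 0.16 at day 4, and centring each array took the list's own median to 0.0038 at that day, with 0.17 at day 6. The list thus did not stand apart at both days. It did so after quantile normalization (0.16 and 0.18) and without x_at and s_at probe sets (0.30 and 0.21). With the mean of a gene's probe sets the day 6 median lay inside the range too (0.09, percentile 93.1). On both days 21 members lay above the median of all genes, against 12.2 expected from matched genes, and 2 lay below it, against 5.80 expected. Differences at day 4 and day 6 were 0.99 and 0.87 for Zmat3, an RNA-binding p53 target, 1.22 and 0.56 for Ephx1, an epoxide hydrolase, 0.77 and 0.75 for Phlda3, an inhibitor of Akt signalling, and 1.07 and 0.40 for Rap2b, a small GTPase. Cdkn1a, which encodes the cell cycle inhibitor p21, differed by 0.63 and 0.77, and Mdm2, the ubiquitin ligase that degrades p53, by -0.23 and 0.29. The senescence and secretory phenotype list, which also holds Cdkn1a, had medians of -0.04 and 0.04 and stayed within the random range, as did apoptosis regulators at 0.20 and 0.07. In the mean of both days, p53 targets were not alone above the random range. Enterocyte (percentile 99.98), enteroendocrine (99.97), unfolded protein (99.9), goblet (99.3), hypoxia (99.25), Paneth (99.1) and fetal genes (98.0) lay there too. Mesenchymal genes (1.37) and the recombined genes (0.15) lay below it. At day 6 the 5' to 3' ratios were also higher in fl/fl organoids, by 0.54 for Actb and 0.35 for Gapdh on the log2 scale.

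The Paneth and goblet cell lists were higher in fl/fl organoids at day 4 and close to the wt/wt level at day 6. Neither stood apart at both days, nor did the unfolded protein list, since each lay within the random range at day 6. Of the Paneth cell list, 12 of 22 members were measured, mostly without the defensins, and their median was 0.63 at day 4 (percentile 100.0) and 0.04 at day 6 (percentile 49.5). Mmp7, the Paneth cell protease, differed by 1.17 and -0.01, and Clps, a colipase, by 0.74 and 0.09. The goblet cell median was 0.46 (percentile 99.99) and 0.03 (percentile 42.7), with 1.29 and -0.21 for the mucin Muc2, 1.16 and 0.19 for Agr2, a disulfide isomerase needed to make mucin, and 1.22 and 0.26 for the hormone precursor Guca2a. The unfolded protein and integrated stress response list was also higher at day 4, with medians of 0.43 (percentile 99.6) and 0.12 (percentile 83.25). The median of its members' own shifts between the days, -0.27, lay inside the random range (percentile 13.6), unlike those of the Paneth and goblet lists. The chaperone gene Hspa5 differed by 1.01 and 0.67 and Herpud1, which acts in the removal of misfolded proteins, by 1.29 and 0.06. Part of the day 4 differences went with the scale, since random lists matched to the Paneth, goblet and unfolded protein lists had medians of 0.16, 0.15 and 0.21. Centring each array took the day 4 medians of these 3 lists to 0.41, 0.25 and 0.21. Mmp7 (0.96), Agr2 (0.95) and Hspa5 (0.80) then fell short of 2-fold. The 5' to 3' ratio of Gapdh was lower in fl/fl organoids at day 4, by 0.55 on the log2 scale, and higher at day 6, by 0.35; that of Actb differed by 0.04 and 0.54.

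At day 6, the lists of absorptive and hormone-producing cell markers were higher in fl/fl organoids and that of stem cell markers lower. None of the enterocyte, enteroendocrine, tuft and stem cell lists stood apart at both days, since each lay within the random range at day 4. The enterocyte median was 0.37 (percentile 100.0), against 0.13 at day 4 (percentile 41.1), with 1.45 at day 6 for the apolipoprotein Apoa4 and 0.95 for the drug-metabolising enzyme Cyp3a11. The enteroendocrine median was also 0.37 (percentile 100.0), against 0.05 at day 4 (percentile 62.0). Among hormone genes at day 6, proglucagon Gcg was higher by 1.47, cholecystokinin Cck by 1.22 and the granule protein Chgb by 1.42; only Gcg among these 3 differed by over 0.5 at day 4, with 0.67. The tuft cell list had medians of -0.11 and 0.19 (percentiles 10.2 and 99.9), with 1.13 for Alox5ap at day 6. The intestinal stem cell median was 0.17 at day 4 (percentile 32.4) and -0.32 at day 6 (percentile 0). Olfm4, a marker of crypt base stem cells, was lower on both days, with differences of -1.06 and -0.91. Lrig1 differed by 1.02 and -0.31. The day 6 arrays are those with the higher 5' to 3' ratios in fl/fl organoids (0.54 for Actb and 0.35 for Gapdh).

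Cell division lists differed by small amounts between the genotypes. Mitosis and G2/M genes had medians of 0.21 and 0.21 (percentiles 27.9 and 99.6), with 0.60 and 0.97 for the centrosomal kinase Nek2 and 0.54 and 0.40 for Tpx2, a spindle assembly factor. TACC3 spindle partners had 0.15 and 0.26 (percentiles 30.7 and 98.2), with 0.63 and 0.37 for the clathrin heavy chain Cltc, and S phase genes 0.11 and 0.09 (percentiles 3.96 and 71.9). With the mean of a gene's probe sets the day 6 median of the spindle partners was 0.0057, inside the random range (percentile 28.5). Wnt/beta-catenin targets had medians of 0.14 and -0.02 within the random range, although Myc differed by 1.11 and -0.14 and Cd44 by 0.88 and -0.21. The remaining lists had these medians at day 4 and day 6: cholesterol synthesis 0.14 and 0.31 (percentile 99.8 at day 6), heat shock and immediate early 0.23 and 0.19 (percentile 98.6 at day 6), fetal and regenerative epithelium 0.28 and 0.06, interferon response -0.02 and 0.07, and Notch pathway 0.10 and 0.05. Markers of other cell types were dim: mesenchymal genes, of which 6 of 17 passed the filter, had -0.23 (percentile 0.46) and 0.00, immune genes -0.14 and 0.05, and endothelial genes -0.04 and 0.05. Sex chromosome transcripts had -0.07 and -0.17 (percentile 1.91 at day 6). The brightest Xist probe set read at most 14.8 on any array, with genotype differences of -0.12 and -0.03. That of Eif2s3y read at least 97.3, with 0.37 and -1.06. Kdm5d differed by -0.01 and -0.19 and Uty by -0.20 and -0.16. Housekeeping genes had 0.17 and 0.25, with the highest day 4 difference, 1.28, for Gusb.

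In all, 169 genes differed 2-fold between genotypes at day 4, 157 higher and 12 lower in fl/fl organoids, and 89 at day 6, 24 higher and 65 lower. The 3 genes shared in the same direction, 1 higher and 2 lower, compare with 0.331 and 0.0685 expected from independent lists, and across the 11392 genes the 2 differences correlated at r = 0.02 (rho = 0.04). Another 4 genes, more than the 3 shared in the same direction, were 2-fold in opposite directions. Of these, 3 were higher at day 4 and lower at day 6 and 1 was the reverse. No expected number was computed for opposite directions. An additive limma fit of genotype and day, with 1 residual degree of freedom, called 0 genes by genotype at an adjusted p under 0.05. The recombined genes were the only one of 26 lists below the random range on both days, with medians of -0.37 and -0.60, and none lay above it on both. That list has 2 members, and Tacc3 (-1.40 and -1.47) alone was lower, since Apc differed by 0.66 and 0.27. It did so no longer after quantile normalization or with the mean of probe sets. The day 4 split depended on scale: it was 114 higher and 38 lower after quantile normalization, and 44 and 47 after centring each array. With these 2 scalings the median difference of the genes above the filter moved from 0.15 to 0.01 and -0.06. Centring also turned the day 4 medians of the mitosis, S phase, spindle partner, Wnt, stem cell, enterocyte, enteroendocrine, apoptosis, cholesterol, Notch and housekeeping lists negative, without moving their percentiles. It left fetal and regenerative genes at 0.06 and heat shock genes at 0.01 on that day.

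**Figure D2:**
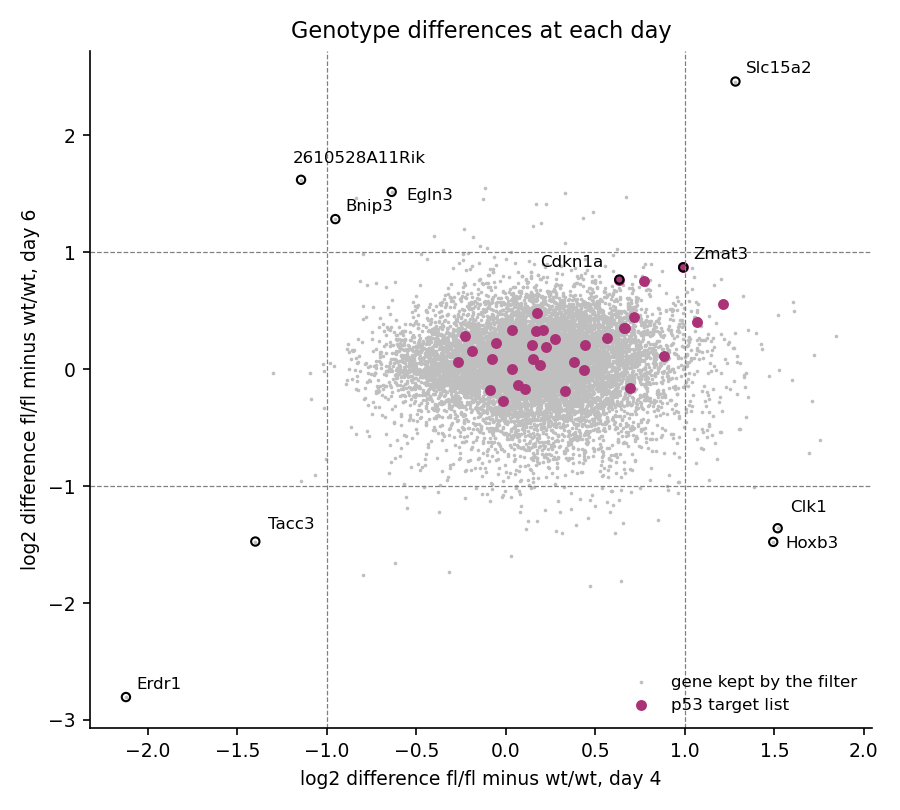
Log2 difference between fl/fl and wt/wt organoids at day 4 (horizontal) and day 6 (vertical) for 11392 genes kept by the filter (grey) and the 34 measured p53 targets (purple), 1 array per group; dashed lines mark 2-fold and circles the labelled genes. Tacc3, Erdr1 and Slc15a2 lie beyond 2-fold in the same direction on both days, and Hoxb3, Clk1 and 2610528A11Rik in opposite directions.

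The comparison of day 6 with day 4 in each genotype addresses what differed between the days. The labels do not settle whether Apc was intact at day 4 and deficient at day 6, or recombined at both. In both genotypes, enterocyte, stem cell and cell cycle genes were higher at day 6, and Paneth cell and fetal or regenerative genes lower. The enterocyte median was 1.43 in wt/wt and 1.97 in fl/fl organoids (both at percentile 100.0), and 22 of 38 members were 2-fold higher in both. The aminopeptidase Enpep was higher by 4.44 and 4.75, the fatty acid binding protein Fabp2 by 2.44 and 3.40, the antimicrobial lectin Reg3b by 4.29 and 3.22 and Cyp3a11 by 2.86 and 3.37. Other genes with the highest day 6 levels relative to day 4 were the selenium carrier Selenop (2.84 and 4.20), the protease Mep1b (3.49 and 3.29), Tmigd1 (3.99 and 2.98), the cytochromes Cyp4f14 (3.38 and 3.45) and Cyp2c55 (3.22 and 3.39), Mgst1 (2.96 and 3.78), the urea cycle enzyme Cps1 (3.07 and 3.41) and the amino acid transporter Slc6a20a (3.42 in fl/fl organoids). The same arrays differed in the 5' to 3' ratios of Actb and Gapdh, each higher at day 6, by 0.99 to 2.06 on the log2 scale.

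The stem cell median was 1.66 in wt/wt (percentile 100.0) and 0.84 in fl/fl organoids (percentile 99.95), with 9 of 20 members 2-fold higher in both; Olfm4 was higher by 2.95 and 3.10, Cdca7 by 2.47 and 2.63 and Lrig1 by 3.03 and 1.70. S phase genes had medians of 1.03 (percentile 99.98) and 0.75 (percentile 99.94), with 9 of 31 members 2-fold higher in both, among them the replication clamp Pcna (1.97 and 2.57), the histone mRNA binding protein Slbp (2.21 and 2.32) and the helicase subunit Mcm4 (2.36 and 1.48). Hells, a chromatin remodeller, was higher by 2.65 and 2.38 on 1 probe set, but after quantile normalization, when another of its probe sets was the brightest, the differences were -0.89 and -0.86. Mitosis genes had medians of 0.79 (percentile 99.6) and 0.77 (percentile 100.0), with 15 of 46 members 2-fold higher and 1 lower in both. With the mean of a gene's probe sets the wt/wt median fell short of the upper bound (0.48, percentile 97.4). After quantile normalization the S phase medians were 0.56 and 0.46 and the mitosis medians 0.37 and 0.53; centring gave 0.64 and 0.55, and 0.41 and 0.56. Ube2c then fell short of 2-fold in wt/wt organoids with both scalings (0.86 and 0.94). On the main scale Top2a was higher by 1.81 and 2.17, Ube2c by 1.32 and 2.18 and Cdk1 by 1.40 and 1.78. TACC3 spindle partners had 0.81 and 0.75 (percentiles 96.2 and 99.2). As with the enterocyte genes, these differences run with the difference in the 5' to 3' ratios.

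Of the lower lists, Paneth cell genes had medians of -0.57 (percentile 0.02) and -1.07 (percentile 0), with -1.42 and -2.07 for Clps and -1.25 and -1.97 for the pentraxin Mptx1. Fetal and regenerative epithelium genes had -0.33 (percentile 0.33) and -0.53 (percentile 0); Ccn2, a target of YAP signalling, differed by -2.20 and -2.20, clusterin Clu by -1.77 and -2.50, mesothelin Msln by -1.84 and -2.38 and Sprr1a by -2.06 and -1.17. Outside the lists, the lowest genes included the cyclooxygenase Ptgs2 (-1.79 and -2.56), the transcription factor Nfia (-2.20 and -1.91), Rbms3 (-1.95 and -1.98), Rapgef6 (-2.12 and -1.71) and Mia3 (-2.01 and -1.70). The growth factor Vegfa (-2.27 and -1.43) and fibronectin Fn1 (-2.05 and -2.97) belong to the hypoxia and mesenchymal lists, whose medians were -0.47 and 0.13 (percentiles 0.05 and 68.1) and -0.43 and -0.08 (percentiles 0.05 and 51.8). The lower lists, like the higher ones, run with the day difference in the 5' to 3' ratios, 0.99 to 2.06 on the log2 scale.

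Wnt/beta-catenin targets as a list did not stand apart. They had medians of -0.04 and -0.11 (percentiles 30.6 and 12.9), with 4 of 30 members 2-fold higher and 1 lower in both genotypes. Higher members were Axin2 (2.26 and 1.04), a feedback inhibitor of the pathway, the growth regulator Myc (2.41 and 1.16) and the receptor-removing ligase Znrf3 (1.87 and 1.33), and the lower one was Nkd1 (-1.90 and -1.76), another feedback inhibitor. After quantile normalization and after centring, Axin2 (0.77 and 0.83) and Myc (0.89 and 0.95) fell short of 2-fold in fl/fl organoids. The goblet cell list had 0.02 and -0.50 (percentiles 28.8 and 0), and p53 targets -0.10 and -0.19 (percentiles 4.18 and 2.42), with -1.70 and -1.18 for Mdm2. Unfolded protein response genes had -0.08 and -0.24 (percentiles 3.82 and 1.83), enteroendocrine genes -0.23 and 0.11, tuft cell genes -0.04 and 0.07 (percentile 97.95 in fl/fl organoids), interferon genes -0.22 and -0.18 (percentile 1.74 in fl/fl organoids), senescence genes -0.16 and -0.12, apoptosis regulators 0.34 and -0.15, cholesterol synthesis 0.41 and 0.38, heat shock and immediate early genes 0.10 and 0.00, and the Notch pathway -0.06 and -0.10. Immune genes had -0.30 and -0.18 (percentiles 3.06 and 2.35), endothelial genes -0.17 and -0.10, and sex chromosome transcripts 0.72 and 0.31 (percentiles 99.6 and 95.8). The recombined genes had 0.76 and 0.52 and housekeeping genes 0.63 and 0.53, within the random range, but B2m was higher by 2.81 and 3.14 and Sdha by 2.01 and 2.06, against 0.14 and 0.29 for Actb and -0.24 and -0.28 for Rpl13a. The other housekeeping members lay between -1.04 (Pgk1, with -0.08 in fl/fl organoids) and 1.86 (Gusb, with 0.89).

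By count, 2420 genes differed 2-fold between the days in wt/wt organoids, 2082 higher and 338 lower at day 6, and 1724 in fl/fl organoids, 1394 higher and 330 lower. In both genotypes 1067 genes were higher and 154 lower, against 255 and 9.79 expected from independent lists, and 0 went in opposite directions; across genes the differences correlated at r = 0.80 (rho = 0.79). The splits depended on scale: after quantile normalization they were 1178 higher and 1092 lower in wt/wt, 924 and 663 in fl/fl and 570 and 412 in both genotypes, and after centring each array 1048 and 1348, 931 and 677, and 562 and 415. With these 2 scalings the median difference of the genes above the filter moved from 0.17 to -0.13 and -0.22 in wt/wt organoids. In fl/fl organoids it moved from 0.00 to -0.12 and -0.21. After quantile normalization the same 4 lists, enterocyte, stem cell, S phase and mitosis, still lay above the random range in both genotypes. Day medians turned negative for the goblet, apoptosis and heat shock lists in wt/wt organoids and for the hypoxia list in fl/fl organoids with both scalings. They also did for cholesterol synthesis in wt/wt and sex chromosome transcripts in fl/fl organoids after quantile normalization, and for the enteroendocrine and tuft lists in fl/fl organoids after centring. The p53 targets lay below the random range in both genotypes after quantile normalization (-0.40 and -0.33) and with the mean of probe sets (-0.14 and -0.16). The mean of a gene's probe sets gave 609 higher and 22 lower in both genotypes. The additive limma fit called 3412 genes by day, 2598 higher and 814 lower. Its only residual is the difference between the genotype differences of the days, so it does not measure the spread between cultures of 1 group. Anything that the 2 arrays of a day share, such as their 5' to 3' ratios, is counted as day.

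**Figure D3:**
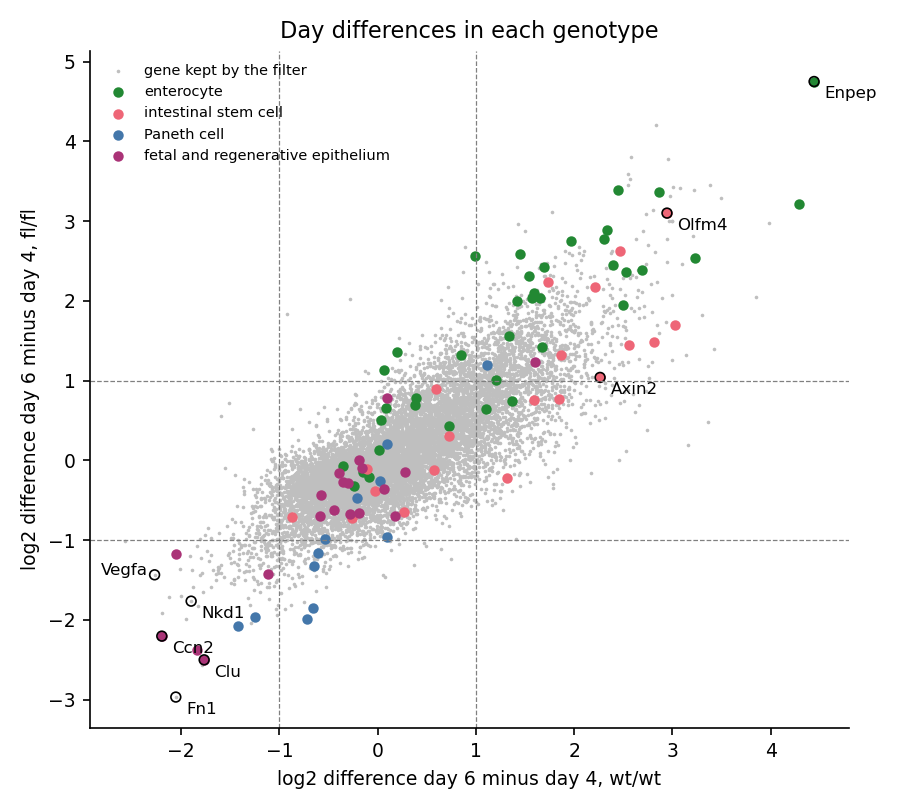
Log2 difference between day 6 and day 4 in wt/wt (horizontal) and fl/fl (vertical) organoids for 11392 genes kept by the filter (grey) and the measured members of 4 gene lists (colours), 1 array per group; dashed lines mark 2-fold and circles the labelled genes. Enterocyte genes extend to the upper right, up to 4.44 and 4.75 for Enpep. Fetal and regenerative genes extend to the lower left, with -2.20 in both genotypes for Ccn2 and with -1.77 and -2.50 for Clu.

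The last comparison asked whether the genotype difference itself was different at the 2 days. Genes of hypoxia and glycolysis stood apart in opposite directions at the 2 days, as no other list did on the main scale; with the mean of a gene's probe sets the tuft cell list did too (-0.13 and 0.15). The 21 measured members had a median genotype difference of -0.13 at day 4 (percentile 0) and of 0.58 at day 6 (percentile 100.0). Without x_at and s_at probe sets the day 4 median was 0.0090, still below the random range (percentile 1.16). At day 4 and day 6 the mitophagy receptor Bnip3 differed by -0.95 and 1.28, the oxygen sensor Egln3 by -0.64 and 1.52, lactate dehydrogenase Ldha by -0.14 and 1.06 and Ankrd37 by -0.23 and 1.20. Their day differences were -1.52, -1.60, -0.10 and -0.79 in wt/wt and 0.72, 0.56, 1.10 and 0.64 in fl/fl organoids. The 5' to 3' ratio of Gapdh, itself a glycolytic gene, differed between genotypes by -0.55 at day 4 and 0.35 at day 6. The median of the members' own shifts, 0.57 for this list, was also positive for enterocyte (0.35, percentile 100.0), enteroendocrine (0.34, percentile 99.95), tuft (0.32, percentile 99.8), mesenchymal (0.26, percentile 99.2), cholesterol synthesis (0.17, percentile 99.9) and mitosis genes (0.02, percentile 99.7). It was negative for Paneth cell (-0.61, percentile 0.03), stem cell (-0.50, percentile 0.2) and goblet cell genes (-0.34, percentile 1.34).

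Single genes with the lowest shifts were Hoxb3 (-2.97) and Hoxb5 (-2.39), homeobox genes of axial patterning, the splicing kinase Clk1 (-2.88), Clca3a1 (-2.46) and the adenylyl cyclase Adcy6 (-2.41). Those with the highest were 2610528A11Rik (2.76), AA467197 (2.30), Bnip3 (2.24), Egln3 (2.15) and the sulfotransferase Sult1b1 (1.79). In all, 541 genes shifted 2-fold, 74 up and 467 down, and the split was 170 and 313 after quantile normalization and 196 and 247 after centring. This difference holds the error of all 4 arrays, and its size was not tested.

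**Figure D4:**
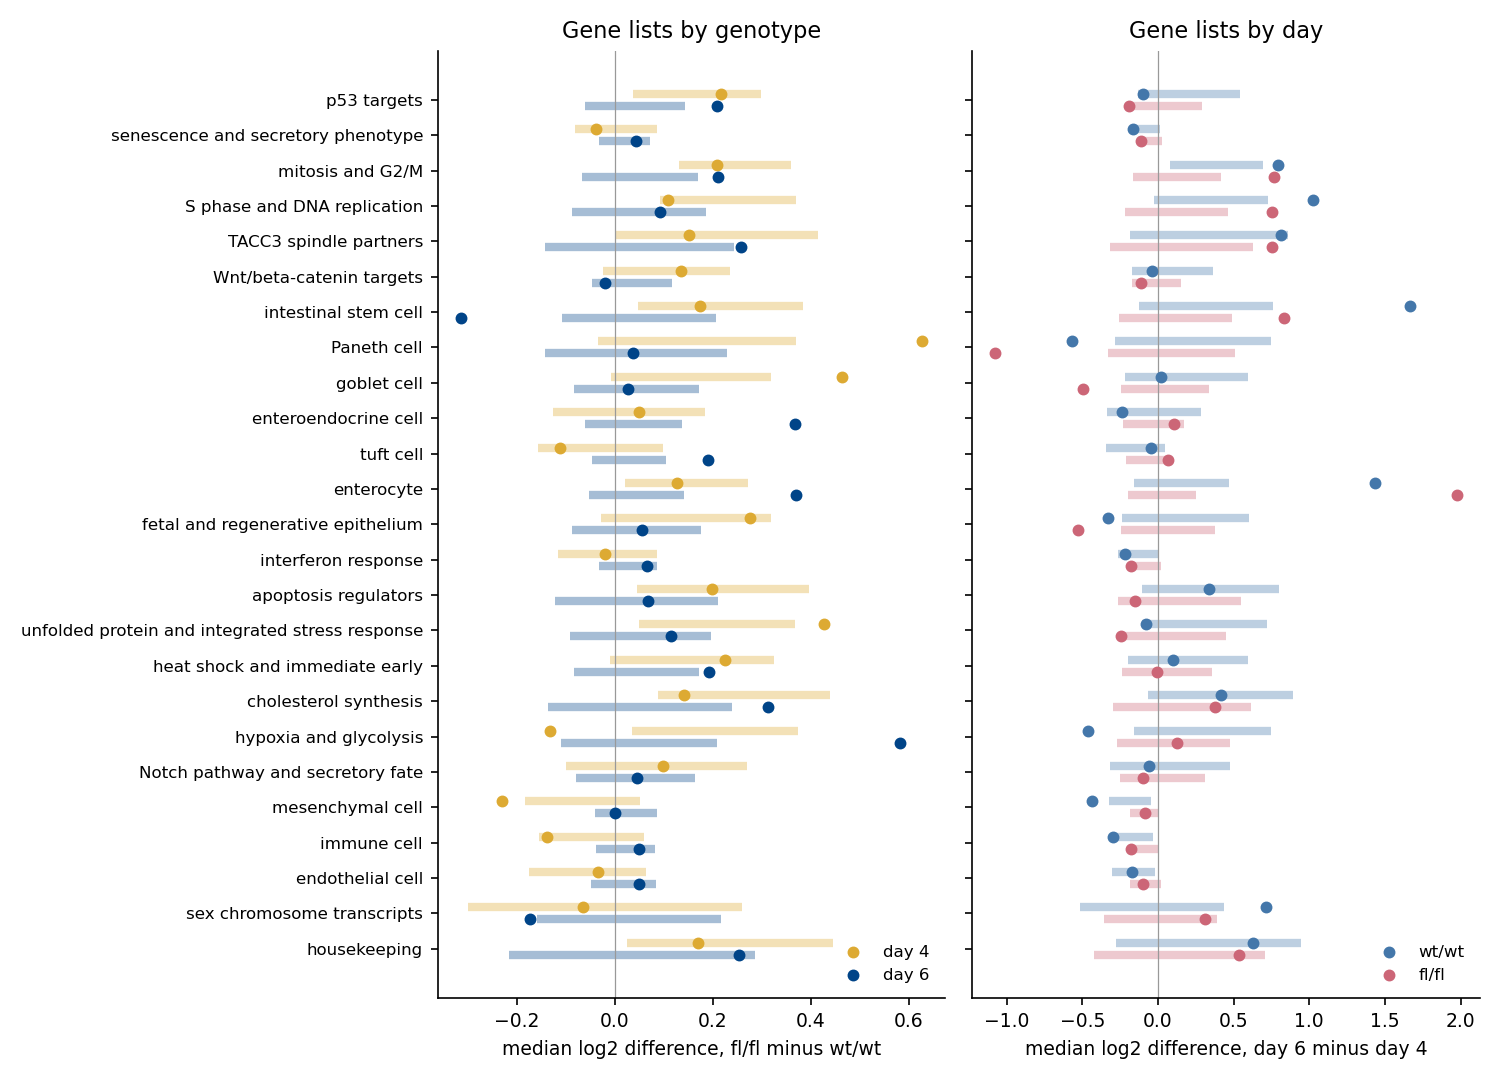
Median log2 difference of the measured members of each gene list, between genotypes at day 4 and day 6 (left) and between days in wt/wt and fl/fl organoids (right); points are list medians from 1 array per group, and bars span the range of 10000 matched random lists outside which a list stands apart, with the recombined genes left out. Hypoxia and glycolysis genes lie below the bar at day 4 (-0.13) and above it at day 6 (0.58), and the enterocyte list lies above it between days at 1.43 and 1.97.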

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

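The tests of RNA integrity, of DNA linked to Tacc3 and of a cross-hybridizing probe set were chosen only after the results were seen; the tests of intensity distribution and of the day trend were not. Genes and lists are given here when the genotype difference went beyond 2-fold, or outside the random range, in opposite directions at the 2 days; none of these shifts was tested, as each day has 1 array per genotype. Hoxb3 differed by 1.49 at day 4 and -1.48 at day 6, a shift of -2.97. Clk1 differed by 1.52 and -1.36, a shift of -2.88. Hoxb5 differed by 1.38 and -1.01, a shift of -2.39. 2610528A11Rik differed by -1.14 and 1.62, a shift of 2.76. The hypoxia and glycolysis list had medians of -0.13 and 0.58, and the median of its members' own shifts was 0.574. Among 2724 probe sets above the filter that the gene table does not list, and that no comparison used, 1445643_at was higher in fl/fl organoids by 1.11 and 1.05, a mean of 1.08.

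Enterocyte and cell cycle lists were higher at day 6 in both genotypes. Different intensity distributions of the arrays do not account for the whole of it, as the lowest of the 6 percentiles of the enterocyte, mitosis and S phase lists was 99.65 after quantile normalization, although in wt/wt organoids that took the mitosis median from 0.79 to 0.37 and the S phase median from 1.03 to 0.56. The mean of each gene's probe sets ended the call of the mitosis list in wt/wt organoids (0.48, percentile 97.4). Lower RNA integrity or shorter labelled cRNA at day 4 stays open: the smallest of the 4 day differences of the 5' to 3' ratio of Actb and Gapdh was 0.985 on the log2 scale, just short of the 2-fold set for it, and with 1 RNA sample per group it cannot be told apart from the day. A different Apc state at the 2 days, as the sample descriptions have it, and growth of the cultures between the days were not tested separately and also stay open.

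The p53 target list was higher in fl/fl organoids in the mean of both days and at day 6, but not apart from random lists at day 4, where its median was 0.0038 after centring each array. Its percentile for the mean genotype difference was 99.51 after quantile normalization, which argues against the intensity distributions as the whole of it. The list's median was 0.14 then and 0.096 after centring. The percentile was 100.0 after a lowess fit of mean genotype difference on mean day difference had been removed. This cannot decide a trend shared with the day axis, which stays open. The 5' to 3' ratio of Gapdh differed between genotypes by -0.55 at day 4 and 0.35 at day 6, so such a trend may cancel in the mean. That of Actb differed by 0.04 and 0.54. The call at day 6 alone was not put to this fit. That fit was small, with a median size of 0.0446 over all genes and 95% of values between -0.049 and 0.220, and at the list's members its median was -0.023, so the list's median went from 0.22 to 0.25. The call at day 6 ended with the mean of each gene's probe sets, where the median was 0.09 (percentile 93.1), and the random lists ignore that p53 targets vary together. In the mean of both days other lists lay further out, among them enterocyte (percentile 99.98) and enteroendocrine genes (99.97). An effect of the Tacc3 genotype, which the design names, and a difference between cultures with no link to Tacc3 were not tested separately and stay open, with 1 array per group.

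Erdr1 and Slc15a2 differed 2-fold between genotypes at both days. DNA linked to the recombined Tacc3 locus would place them near Tacc3, and 0 of the 2 genes are among the 50 named genes on either side of it in the GRCm38.p6 annotation; the 100 neighbours had a median absolute difference of 0.11 (percentile 3.93). A single probe set that cross-hybridizes stays open: 0 of the 2 genes had another probe set above the filter that was 2-fold on both days. Only 1 other probe set above the filter existed to be asked, that of Erdr1, and at day 6 it read 20.2 in wt/wt and 13.5 in fl/fl organoids, near the filter. A difference in strain background between the cultures, and an effect of Tacc3 itself, were not tested and stay open.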

How the results depend on the processing

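The test with list members above the filter was chosen after the data had been seen; all other alternatives were planned. No paired analysis by replicate was possible because each group has 1 array. The additive limma fit takes the day as a block. Pairing the genotypes across days gave the same 3 genes, Erdr1, Slc15a2 and Tacc3. What signal over background limits is shown by the pseudocount, which moved counts in dim genes. The cause was not tested where none is named below.

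Counts follow the order genotype at day 4, at day 6 and at both days, day in wt/wt, in fl/fl and in both, and shift between days; those within 1.5 times of the main count are left out, among them all counts without a low-value filter, with one at the 70th percentile, without x_at and s_at probe sets and with values raised to the 20th percentile. At 1.5-fold all 7 were larger by construction, at 1543, 788, 75, 5198, 4083, 2997 and 2441, and at 3-fold smaller, at 9, 9, 1, 735, 457, 276 and 65. The mean of a gene's probe sets gave 75, 45, 1, 1299, 927, 631 and 263. Pseudocount 64 gave 27 and 37 by genotype at each day, 1201, 856 and 588 by day and 180 for the shift, and pseudocount 1 gave 523, 161, 6 and 1101 for the genotype counts and the shift. Centring gave 91 at day 4. Quantile normalization gave 5 genes at both days, the same 3 with Dnajc17 and Mid1, named here after their values were seen. Erdr1 left that count without x_at and s_at probe sets, Slc15a2 with pseudocount 64, and Slc15a2 and Tacc3 with the mean of probe sets. The additive limma fit called 0 genes by genotype (609 at an unadjusted p under 0.05; adjusted p = 0.784 for Tacc3) and 3412 by day (2598 higher, 814 lower; 5058 unadjusted).

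With the mean of probe sets, Tacc3 fell short of 2-fold at -0.716 and -0.747 and Apc between days at 0.433 and 0.349, since their probe sets differ; Apc in fl/fl organoids gave 0.862 with pseudocount 64. Hells between days turned to -0.886 and -0.865 after quantile normalization and to -0.438 and -0.714 with pseudocount 1, because another of its probe sets became the brightest.

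The p53 list entered the upper range at day 4 after quantile normalization (0.162) and without x_at and s_at probe sets (0.304), so that it then stood apart at both days, and left it at day 6 with the mean of probe sets (0.0927). Between days it crossed the lower bound in wt/wt organoids at -0.403 (quantile), -0.142 (mean) and -0.0826 (members above the filter), and lay above it in fl/fl organoids at -0.144 (no x_at or s_at), -0.0967 (pseudocount 64) and -0.144 (members above the filter). Wnt targets entered at day 4 at 0.140 (quantile), S phase genes at 0.218 at day 6 and 0.259 in the mean (no x_at or s_at), and mitosis genes at 0.264 in the genotype mean (pseudocount 1). With the mean of probe sets, mitosis genes between days in wt/wt organoids went below the bound at 0.483 (percentile 97.4), and TACC3 spindle partners at day 6 turned to 0.00572, inside the random range. With centring left out, since it cannot move a list's percentile, 50 list medians outside the random range gave 350 values, of which 304 stayed outside on the same side, 45 lay inside and 1 crossed the middle of the random lists. With centring included, 194 differences of 2-fold in named genes gave 1358 values, of which 1159 stayed 2-fold, 195 did not and 4 turned. Part of those that stayed could hardly have moved. Raising values to the 20th percentile barely touches genes above the filter, and pseudocount 1 enlarges a difference unless another probe set becomes the brightest. By day, 3 lists came to lie below the random range in both genotypes: p53 targets (quantile normalization, mean of probe sets), immune cell genes (values raised to the 20th percentile) and mesenchymal genes (members above the filter).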

Other observations

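Probe sets without a gene in the platform's table also separated the genotypes at both days. Of 2724 such probe sets above the filter, 5 were 2-fold apart in the same direction at both days, 4 of them lower in fl/fl organoids. Probe set 1427820_at went from 682 and 654 in wt/wt to 37.9 and 17.3 in fl/fl organoids (-3.70 and -4.33). Probe set 1439200_x_at differed by -1.88 and -2.51. The bright probe sets 1431213_a_at (12584 and 10975 against 4219 and 3984) and 1455869_at (14810 and 13451 against 4635 and 4390) differed by -1.57 and -1.46 and by -1.67 and -1.61.

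Mid1, named here after its values were seen, is the nearest gene above the filter to Erdr1 in the GRCm38.p6 annotation of the X chromosome. It was also lower in fl/fl organoids, with -0.80 at day 4 and -1.76 at day 6, while the next such gene, Hccs, differed by 0.68 and 0.46. At a 1.5-fold threshold, 61 genes were higher and 14 lower in fl/fl organoids on both days, against 42.5 and 8.19 expected from independent lists, and 3 of the 30 p53 targets above the filter were among those higher.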
